A study of Mus musculus with 8 samples.

How the data were processed

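Single cells of the extraembryonic yolk sac of wild-type C57BL/6N mice at embryonic day 9.5 were measured in 8 libraries of 192 wells each, 4 labelled as A1 and A2 cells and 4 labelled as EMP cells (erythromyeloid progenitors). Per the labels' protocols, cells were stained for CD45 and CD11b, CD45-positive cells were sorted singly into 384-well plates, and libraries were made with mCEL-Seq2, a method that tags each transcript at its 3' end with a well barcode and a random molecular identifier. Per the submitters' processing notes, BWA 0.6.2-r126 and Seurat were used. Their roles are not stated, and the genome build, the annotation and the rule for reads shared between near-identical genes are not given in the sources used here, so no coordinates are given.

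The values the authors deposited are estimated counts of transcripts per gene and well, not scaled for depth. Per the values themselves, every entry (100% in each library, at a tolerance of 1e-06) returns a whole number of identifiers when the usual correction for collisions among 4096 identifiers is undone. The deposited per-library tables hold all 1536 wells and were used throughout. A deposited series table of the same estimated counts holds 689 wells of the A1/A2 libraries with values identical to the per-library tables, and a note deposited with it says that damaged cells were left out before Seurat was run. In the 4 libraries, the wells held there had totals of at least 501.598, 499.323, 526.48 and 536.252 transcripts, and the highest total among wells not held was 496.267. The tables list 23091 genes by symbol and no spike-in entries (0).

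Cells with at least 1000 transcripts were kept. Estimated counts were summed per library, or per library and class of cells, and rounded to whole numbers, because cells of a library are not replicates. Sums were tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit, TMM normalization, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment at 5%. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Levels are given as CPM (counts per 1e6 of the TMM-scaled sums).

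There were 3 comparisons. A1/A2 libraries were compared with EMP libraries without a block, so libraries of the same number were not paired. Within the A1/A2 libraries, cells with a Cx3cr1 and no Kit transcript were compared with cells with a Kit and no Cx3cr1 transcript, with library as a block and without Cx3cr1 and Kit among the genes tested. These transcripts stand in for the gates of A2 and A1 cells, which share libraries and carry no label per well. Among the first class, cells with and without an Mrc1 transcript were compared in the same way, also without Mrc1. A sum of the last comparison was made only from 5 or more cells. No rule on a minimum was set for the Kit sums, the smallest of which holds 4 cells in the main setting and 1 cell without cells of other lineages.

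Gene lists (19) of lineages, macrophage subsets and cell states were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists with 3 or more tested members. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, are given beside it. Shares of cells with a transcript were compared after thinning each cell to 1000 transcripts, which left out none of the kept cells (568 A1/A2 and 655 EMP), with a two-sided exact permutation test over the 70 assignments of the 8 libraries, adjusted over 10 genes.

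Cells of each group of libraries were clustered apart with scanpy 1.11.5 and leidenalg 0.10.2 (log of counts per 10000, 2000 variable genes, 20 components, 15 neighbours, resolution 0.6). A cluster was named after a list, with the ending -like, when the list had the most members among its raised genes, at least 3 of them, and at least 1 member among the first 10 genes by fold, where no other list had more. Between lists with as many raised members, as for cluster 3 of the A1/A2 libraries, the one with more members among the first 10 was taken. No caller for doublets was run, because cells were sorted singly. Cluster sizes were not compared between groups.

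Tests, lists, the cell filter and most alternatives were fixed before the data were examined. So was the rule for naming genes: 10 marker genes of the sorted cells, the 10 higher and 10 lower genes with the largest change among those past 5%, with a mean of at least 50 CPM in the higher group and the same direction in every library number, and up to 4 members per list with the smallest p. Unnamed predicted genes, ribosomal protein genes and mitochondrial genes were counted and not named. After the values were seen, the names taken from lists were limited to the first and second member by p of each list past the threshold of camera, and the naming rule was otherwise kept, except that the text leaves out 3 of the genes it picked.

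The tests were run on simulated counts drawn from the real means and library sizes, with 200 changed genes in each of 10 draws. Of genes changed 4-fold, 97.5% were recovered for the A1/A2 and EMP libraries (11144 genes), 84.6% for the Cx3cr1 and Kit classes (8674 genes) and 96.7% for the Mrc1 classes (8184 genes). Of genes changed 2-fold, the shares were 75%, 30.2% and 61.5% in the same order. False calls made up 5.75% ± 2.12 (SD over draws), 11.3% ± 2.49 and 9.99% ± 2.55 of the calls, above the nominal 5% by most for the Cx3cr1 and Kit classes and the Mrc1 classes.

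The labels name no animals or litters, so p-values measure only the spread between libraries, which may be technical. All libraries carry the same batch label, so no batch could be compared. Libraries of a group differed by more than counting noise (chi-square over degrees of freedom of 4.44 to 12.0 in 12 pairs), so none was treated as a repeat of another. Intervals and limits from a count of 0 cover counting error only; a count of 0 cells allows up to 3 cells.

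Alternatives were DESeq2 1.42.0, other normalizations, no filter on low counts, other cell filters, thinning, leaving out each library, adding or dropping the block, other class definitions and other list tests. Alternatives chosen after the data were seen were the use of identifiers in place of estimates, leaving out cells of other lineages, thinning to 10000 transcripts, and other normalizations of the list tests. Cells of other lineages are those of the named clusters except the progenitor-like one, and of cluster 6 of the A1/A2 libraries. The other clusters without a name, such as clusters 0, 1 and 5 of the A1/A2 libraries, stayed in. The first draft of the simulation used a single draw; it was replaced by 10 draws for a steadier estimate.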

Results

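The data were single-cell transcript counts of the mouse yolk sac, the site where the earliest blood cells and macrophages form. The 8 libraries fell into 2 groups of 4. The A1/A2 libraries hold myeloid progenitors at embryonic day 9.5. A1 cells are known as Kit-positive and Cx3cr1-negative, and A2 cells, which derive from them, as Cx3cr1-positive. The EMP libraries hold erythromyeloid progenitors, from which A1 cells arise, and were run beside the A1/A2 libraries but, per the labels, not used in the published work. Of 1536 wells, 1223 passed 1000 transcripts, 568 of 768 in the A1/A2 libraries and 655 of 768 in the EMP libraries. Kept cells per library numbered 132, 143, 127 and 166 in A1/A2 libraries 1 to 4, and 170, 177, 161 and 147 in EMP libraries 1 to 4. Total transcripts of kept cells were 2558197, 3559612, 2752725 and 3447313 in the A1/A2 libraries and 4893170, 5418136, 5349792 and 3888853 in the EMP libraries. The median kept cell held 6153 transcripts in the A1/A2 libraries and 20369 in the EMP libraries.

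The A1/A2 libraries held cells with Cx3cr1 and Csf1r transcripts beside cells of several other lineages. Clustering of the 568 cells gave 9 clusters. Cluster 1 (102 cells, 17.96% ± 4.16 of kept cells per library, SD, n = 4) was led by Lpl, Ccnd2 and Coro1a, with Cx3cr1 and Spi1, the transcription factor of myeloid cells, further down, and stayed without a name: 4 macrophage genes were raised in it, but its first 10 genes by fold held none of them and 1 granulocyte and monocyte gene, Prtn3. In it, 92.2% of cells had a Cx3cr1 transcript, 99.0% a Csf1r transcript and 62.7% an Mrc1 transcript, at a median total of 44110 transcripts. Cluster 2 (78 cells) was yolk sac endoderm-like, cluster 4 (58 cells) erythroid-like and cluster 8 (18 cells) mesenchyme-like. Cluster 3 (62 cells, 11.04% ± 6.27) was granulocyte_monocyte-like and led by S100a8 and S100a9, genes of neutrophils. In it, 3 granulocyte and monocyte genes and as many macrophage genes were raised, and 2 and 0 of these were among its first 10 genes by fold. Cluster 6 (26 cells, 4.82% ± 4.15) had no name and was led by Lyz1, Ly6c2 and Ccr2, genes of monocytes. Cluster 7 (18 cells, 3.34% ± 2.63) was lymphoid-like and led by immunoglobulin genes. Cluster 5 (27 cells) had a median total of 85073 transcripts and was led by ribosomal protein genes and Prtn3. Cluster 0, the largest (179 cells), was shallow, with a median of 1931 transcripts, and had no name. For background, 25.6% of the endoderm-like cells had a Cx3cr1 transcript, 62.8% a Csf1r transcript and 33.3% an Mrc1 transcript at a median total of 33949 transcripts. The EMP libraries, clustered apart, gave 7 clusters, among them progenitor-like (112 cells), endothelial-like (90 cells), endoderm-like (155 cells), erythroid-like (13 cells) and mesenchyme-like (12 cells) ones, and 2 without a name (211 and 62 cells).

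**Figure D1:**
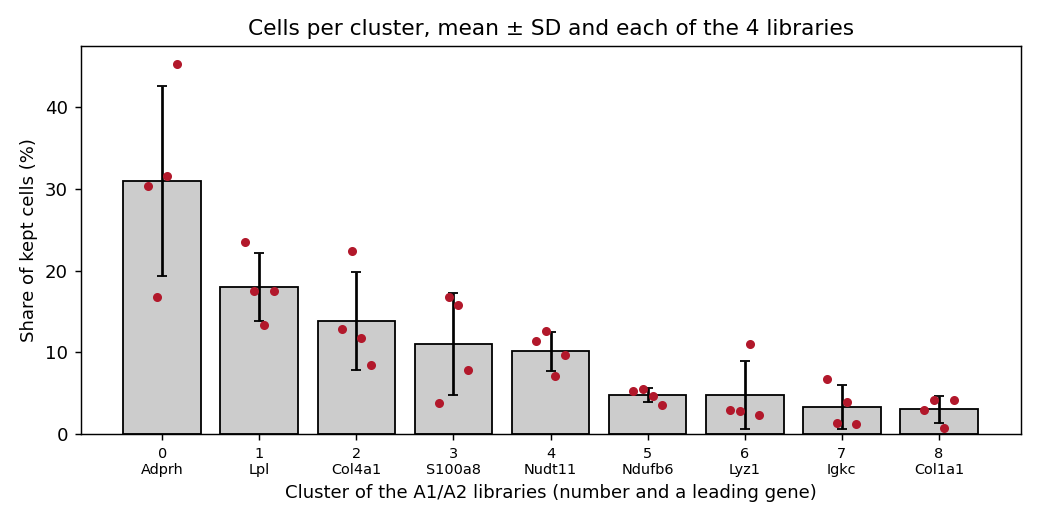
Share of kept cells (%, vertical axis) in each of the 9 clusters of the A1/A2 libraries (horizontal axis, number and a leading gene). Bars give the mean of 4 libraries, error bars the SD and points the single libraries; cluster 1, led by Lpl, held 17.96% of cells.

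The comparison of A1/A2 with EMP libraries asked how the myeloid precursors differ from the progenitors upstream of them. The sums hold all kept cells, however. Of 655 EMP cells, 112 were progenitor-like, 155 endoderm-like and 90 endothelial-like. Of 568 A1/A2 cells, 78 were endoderm-like, and no cluster was endothelial-like. A difference may thus reflect the mix of cells. Endothelial and endoderm lists stayed lower by camera without cells of other lineages, but clusters without a name stayed in there. By camera at its preset correlation, macrophage genes were higher in the A1/A2 libraries and progenitor, megakaryocyte and endothelial genes were lower. With an estimated correlation the macrophage call held (adjusted p = 0.0482) and the other lists did not pass (adjusted p = 0.283 for progenitor and 0.119 for megakaryocyte and endothelial genes). Csf1r, the receptor for the main growth factor of macrophages, rose from 18.4 ± 3.53 to 205 ± 23.5 CPM (SD, n = 4 each; log2 fold change 3.47 ± 0.14, SE; adjusted p = 5.80e-08). Cx3cr1, the fractalkine receptor, rose from 3.18 ± 1.42 to 110 ± 28.6 CPM (5.07 ± 0.26 on the log2 scale). Kit, the stem cell factor receptor, fell from 55.3 ± 14.9 to 12.2 ± 1.68 CPM (log2 fold change -2.18 ± 0.22; adjusted p = 3.84e-05). In all, edgeR called 3651 of 11144 genes, 1931 higher and 1720 lower in the A1/A2 libraries, and 1074 of them changed at least 2-fold, 754 up and 320 down.

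Of the 10 marker genes, 7 rose, 1 fell and 2 did not pass, and the counts were the same adjusted over the list alone. Ptprc, which encodes CD45, rose by 3.14 ± 0.26 on the log2 scale, Itgam, which encodes CD11b, by 3.10 ± 0.19, Mrc1, which encodes CD206, by 2.61 ± 0.27 and Spi1 by 2.20 ± 0.28. Adgre1, which encodes F4/80, had only 3 counts in the EMP libraries against 87, a ratio of 46.0 with a 95% counting interval of 15.2 to 228. Cd34 differed by -0.30 ± 0.33 (adjusted p = 0.518) and Runx1 by -0.25 ± 0.25 (adjusted p = 0.478), but without cells of other lineages Runx1 was at -0.65 ± 0.19 (adjusted p = 0.0197). The marker list passed the camera test (adjusted p = 6.36e-05; adjusted p = 0.119 with an estimated correlation). Its genes were chosen as those that define the sorted cells, and CD45 and CD11b were stained for the sort. Their differences may thus follow from the sort and are no independent support.

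**Figure D2:**
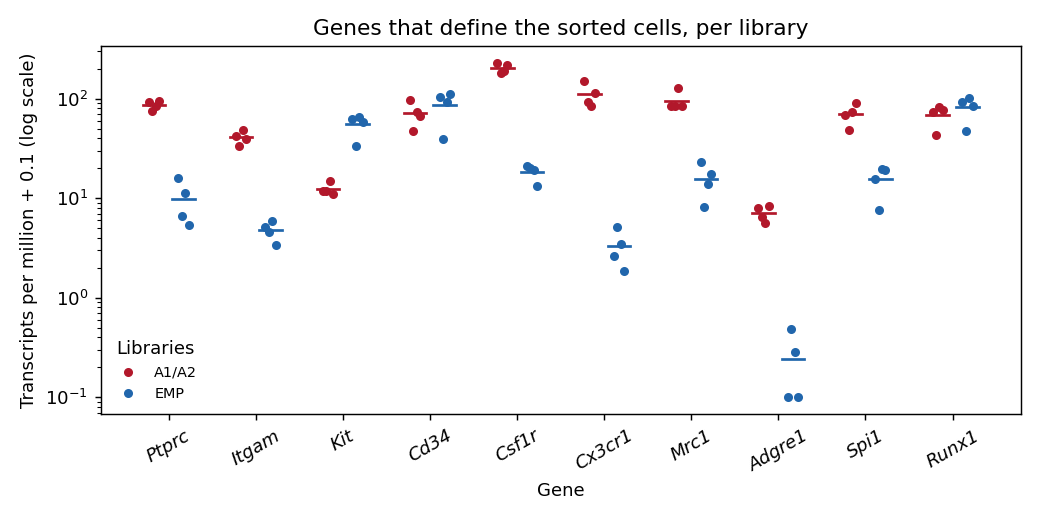
Level of the 10 marker genes (CPM plus 0.1, log scale, vertical axis) in each A1/A2 library (red) and each EMP library (blue), with a bar at the mean. Points of both groups overlap for Cd34 and Runx1, and Csf1r is at 205 CPM on average in the A1/A2 libraries against 18.4 in the EMP libraries.

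Among genes with a mean of at least 50 CPM in the higher group that moved the same way in every library number, the highest by fold besides Cx3cr1 were Cd74 (7.21 ± 0.93 on the log2 scale), Ccl3 (6.09 ± 0.47), H2-Aa (4.95 ± 0.72), Ccl6 (4.74 ± 0.35), Cybb (4.61 ± 0.40), C1qb (4.60 ± 0.35), C1qc (4.46 ± 0.37), Lpl (3.88 ± 0.44) and Cd52 (3.78 ± 0.28). Cd74 and H2-Aa serve antigen presentation by MHC class II, C1qb and C1qc encode complement chains made by macrophages, and Cybb encodes a subunit of the phagocyte oxidase. Under the same limits, the lowest besides Kit were Plvap (-3.73 ± 0.41), Mycn (-3.07 ± 0.22), F2r (-2.41 ± 0.26), Tie1 (-2.33 ± 0.25), Ikzf2 (-1.81 ± 0.40), Adgrg1 (-1.78 ± 0.30), Lyve1 (-1.60 ± 0.44), Nrgn (-1.57 ± 0.23) and Timp3 (-1.48 ± 0.21). Plvap and Tie1 are endothelial genes, and Lyve1 marks lymphatic and yolk sac endothelium as well as some macrophages. Lyve1 passed by little: its adjusted p was 0.0510 to 0.0779 without A1/A2 library 1, 2 or 4 or without EMP library 1, 3 or 4, and without cells of other lineages it was at -0.92 ± 0.63 (adjusted p = 0.313).

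Of 18 lists with enough members, 8 were higher and 4 lower by camera. Without cells of other lineages 6 were higher and 6 lower: antigen presentation and dissociation stress genes lost the call, and erythroid and mesenchyme genes were called lower. The clusters left out there were named by lists tested here, the erythroid, mesenchyme, endothelial and endoderm ones included. Calls of these lists in that setting are thus not independent of the filter. Macrophage genes rose in 17 of 22 measured members, and none fell (17 also adjusted over the list alone; adjusted p = 5.59e-11), with Fcgr1, an antibody receptor, up by 4.26 ± 0.25. This call alone held with an estimated correlation (adjusted p = 0.0482). Granulocyte and monocyte genes rose in 7 of 7 (7 adjusted over the list alone; adjusted p = 6.06e-06), with Igsf6 up by 4.55 ± 0.27 and F13a1 by 2.77 ± 0.27. Chemokine and inflammation genes rose in 5 of 7 (5 adjusted over the list alone; adjusted p = 6.36e-05), with Ccl9 up by 3.85 ± 0.28. Microglia genes rose in 5 of 9 and fell in 1 (the same adjusted over the list alone; adjusted p = 0.00348), with Fcrls up by 4.08 ± 0.40. Genes of the stress of dissociation rose in 5 of 15 and fell in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.00764), with Jun up by 1.35 ± 0.14 and Klf2 by 2.12 ± 0.23. With an estimated correlation, each of these 4 lists had an adjusted p = 0.119. Antigen presentation genes rose in 4 of 4 (4 adjusted over the list alone; adjusted p = 0.000303; adjusted p = 0.179 with an estimated correlation). Cd74, H2-Aa, H2-Ab1 and H2-Eb1 were also among the leading genes of the lymphoid-like cluster of the A1/A2 libraries, and without cells of other lineages H2-Aa was up by 2.97 ± 0.57 in place of 4.95 ± 0.72. Ribosome biogenesis genes rose in 13 of 20 (14 adjusted over the list alone; adjusted p = 5.29e-05; adjusted p = 0.216 with an estimated correlation), with Nop58 up by 0.55 ± 0.11 and Nop16 by 0.51 ± 0.11.

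Endothelial genes fell in 12 of 15 and rose in 1 (the same adjusted over the list alone; adjusted p = 1.43e-07), with Esam at -3.73 ± 0.33 and Ramp2 at -1.35 ± 0.15 on the log2 scale. Megakaryocyte genes fell in 7 of 9 (8 adjusted over the list alone; adjusted p = 9.70e-05), with Itga2b at -1.47 ± 0.25. Both lists had an adjusted p = 0.119 with an estimated correlation. Progenitor genes fell in 10 of 16 and rose in 1 (12 and 1 adjusted over the list alone; adjusted p = 3.14e-05; adjusted p = 0.283 with an estimated correlation), with Erg at -4.06 ± 0.38. Yolk sac endoderm genes fell in 12 of 19 (17 adjusted over the list alone; adjusted p = 3.22e-05; adjusted p = 0.396 with an estimated correlation), with Fgb at -0.92 ± 0.20 and Hnf4a at -0.82 ± 0.18. The other lists did not pass. Erythroid genes fell in 3 of 15 (3 adjusted over the list alone; adjusted p = 0.0719) and mesenchyme genes in 3 of 13 (2 adjusted over the list alone; adjusted p = 0.0918). Mast cell and basophil genes rose in 1 and fell in 1 of 4 (adjusted p = 0.521), proliferation genes rose in 4 and fell in 4 of 20 (adjusted p = 0.649), and both counts were the same adjusted over the list alone. Lysosome genes rose in 6 and fell in 4 of 20 (the same adjusted over the list alone; adjusted p = 0.714), with a median log2 fold change of -0.04 and a mean of 0.12. Genes of macrophages at the borders of the central nervous system rose in 4 and fell in 3 of 11 (the same adjusted over the list alone; adjusted p = 0.984), with a median of -0.44, a mean of 0.34, a camera direction down and a fry direction up. Of the lymphoid list 1 gene was tested and it rose, also adjusted over the list alone.

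The count of calls fell without deep wells. Without cells above 3 times the median total of their library, edgeR called 786 genes, 598 higher and 188 lower, and 637 of these were among the 3651; of 3186 of the 3651 still tested, 460 changed sign. With every cell thinned to 1000 transcripts it called 121 of 2395 genes tested, 94 higher and 27 lower, and 114 were among the 3651; of 972 still tested, 130 changed sign. The first of these filters takes out cell types along with depth, since the median cell of cluster 1 of the A1/A2 libraries held 5.18 times the median total of its library. These values do not part depth from cell type.

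Shares of cells with a transcript, at 1 depth of 1000 transcripts per cell, asked the same question per cell. Csf1r was found in 18.2% ± 4.96 of A1/A2 cells against 2.01% ± 0.824 of EMP cells (SD, n = 4 libraries each). Ptprc was found in 9.33% ± 2.06 against 0.904% ± 0.732, Mrc1 in 8.56% ± 2.05 against 2.32% ± 1.40, Cx3cr1 in 7.26% ± 3.47 against 0.302% ± 0.349 and Itgam in 4.48% ± 1.01 against 0.599% ± 0.508. Kit was found in 0.846% ± 0.981 of A1/A2 cells against 6.39% ± 2.14 of EMP cells, and Runx1 in 5.78% ± 0.816 against 9.30% ± 2.48. For each of these 7 genes the libraries of both groups did not overlap, and the exact permutation test gave its smallest possible p, 0.0286 (adjusted p = 0.0408). Cd34 (4.67% ± 1.69 against 7.60% ± 3.43; exact permutation p = 0.229, adjusted p = 0.229), Spi1 (3.80% ± 1.47 against 2.03% ± 0.957; exact permutation p = 0.114, adjusted p = 0.143) and Adgre1 did not pass. Adgre1 was in 1.23% ± 1.06 of A1/A2 cells and in 0 of 655 EMP cells, which allows a share of up to 0.458% (exact permutation p = 0.143, adjusted p = 0.159).

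As background, endoderm-like cells thinned in the same way had a Csf1r transcript in 6.41% of A1/A2 cells, an Mrc1 or Runx1 transcript in 2.56%, and an Itgam or Cx3cr1 transcript in 1.28%. For Ptprc, Kit, Cd34, Adgre1 and Spi1 it was 0 of 78 such cells, which allows up to 3.85%. In the EMP libraries the endoderm-like background was 0.645% for Mrc1 and 1.29% for Runx1 and Spi1, and 0 of 155 cells for the other 7 genes, which allows up to 1.94%. The Kit, Spi1 and Adgre1 shares of A1/A2 cells and the Ptprc, Itgam and Cx3cr1 shares of EMP cells lie below these limits, so no expression is read from them. Without thinning, Csf1r was found in 57.5% ± 2.57 of A1/A2 against 25.1% ± 4.16 of EMP cells, Cx3cr1 in 34.4% ± 4.64 against 4.74% ± 1.26, Kit in 12.8% ± 1.63 against 41.6% ± 7.15, Runx1 in 36.6% ± 2.40 against 43.8% ± 9.27 and Mrc1 in 29.7% ± 4.63 against 16.8% ± 5.85. The call of Runx1 was lost without thinning (exact permutation adjusted p = 0.257) and at 2000 transcripts per cell (0.143), so it rests on the depth chosen; Adgre1 passed without thinning and Spi1 at 2000 transcripts (0.0408 each). Without A1/A2 library 1, 3 or 4, 0 of the 10 genes passed, but with the 35 assignments left at least 6 genes must reach the smallest possible p for any to pass, so this does not show that a call rests on 1 library.

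Within the A1/A2 libraries, the comparison of cells with a Cx3cr1 and no Kit transcript with cells with a Kit and no Cx3cr1 transcript asked what separates A2 from A1 cells. By camera at its preset correlation, macrophage genes were higher in the Cx3cr1 cells and lists of erythroid, progenitor and endoderm genes were lower, though under 50% of the members of these 3 lower lists passed one by one. With an estimated correlation none of these 4 calls held (adjusted p = 0.284 for macrophage and progenitor, 0.343 for erythroid and 0.381 for endoderm genes). Mrc1 rose from 14.4 ± 8.30 to 149 ± 84.4 CPM (SD, n = 4 libraries; log2 fold change 3.57 ± 0.36, SE; adjusted p = 1.29e-08), and Lpl, which encodes lipoprotein lipase, from 68.2 ± 25.9 to 732 ± 147 CPM (3.45 ± 0.23; adjusted p = 1.82e-13). With cells thinned to 10000 transcripts before classes were set, the fold change of Mrc1 was 0.78 ± 0.94 (adjusted p = 0.902), that of Lpl 1.68 ± 0.45 (adjusted p = 0.6005) and that of Ccl3 0.70 ± 0.47 (adjusted p = 0.836). These differences are thus not shown at equal depth, but the thinned classes hold other cells. The thinned Kit class had 5, 2, 4 and 7 cells in libraries 1 to 4, with median totals before thinning of 37355 to 82183 transcripts. A smaller fold there cannot be read as an effect of depth alone. Gata2, a transcription factor of progenitors and mast cells, was at 65.7 ± 99.1 CPM in the Kit cells, with 214 CPM in library 3, and at 4.73 ± 4.82 CPM in the Cx3cr1 cells (-3.60 ± 0.55; adjusted p = 2.38e-05; 0.121 without library 3). In all, edgeR called 544 of 8674 genes, 320 higher and 224 lower in the Cx3cr1 cells. The balance of the 2 directions turned with the method: DESeq2 called 119 higher and 169 lower, cells required to have Csf1r gave 409 and 446, and library totals gave 429 and 207. There were 153 Cx3cr1 cells but only 30 Kit cells (4, 8, 10 and 8 in libraries 1 to 4), with median totals of 33646 and 12931 transcripts. Left out were 43 cells with both transcripts, at a median total of 51248, and 342 cells with neither. In cluster 1, 25 of 102 cells had a Kit transcript, but only 1 of these was in the Kit class. The Kit class is thus a poor stand-in for A1 cells.

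The Kit class was mixed. Of its 30 cells, 9 lay in the endoderm-like cluster, 10 in the shallow cluster 0 and 1 in cluster 1, while 70 of the 153 Cx3cr1 cells lay in cluster 1. Of all endoderm-like cells, 16.7% had a Kit transcript, against 12.8% ± 1.63 of all A1/A2 cells. Of the 7 marker genes tested, 5 rose and none fell (6 adjusted over the list alone; camera adjusted p = 0.00131; adjusted p = 0.360 with an estimated correlation). Csf1r rose by 2.26 ± 0.24, Spi1 by 2.02 ± 0.39, Itgam by 1.51 ± 0.43 and Ptprc by 1.21 ± 0.32 on the log2 scale, while Cd34 differed by 0.85 ± 0.32 (adjusted p = 0.109) and Runx1 by -0.34 ± 0.25 (adjusted p = 0.499). Without cells of other lineages Runx1 was at -1.68 ± 0.44 (adjusted p = 0.0161), and Spi1 (0.99 ± 0.56, adjusted p = 0.674), Itgam (1.498 ± 0.744, adjusted p = 0.547) and Ptprc (1.22 ± 0.58, adjusted p = 0.512) lost the call. In this setting the Kit sums of libraries 1 to 4 held only 1, 2, 4 and 6 cells, with 2721 transcripts in library 1. Cluster 0, which held 10 of the 30 Kit cells, was kept there. Calls gained or lost in this setting rest on those few cells. With cells thinned to 10000 transcripts the values were 1.11 for Csf1r, 0.43 for Spi1, -0.45 for Itgam and 0.24 for Ptprc. Plekho1 had only 3 counts in the Kit cells against 290, a ratio of 15.1 with a 95% counting interval of 5.12 to 73.7. Among the other genes with a mean of at least 50 CPM in the higher class that moved the same way in every library, leaving out genes known only by a clone number, the largest rises were those of Ccl3 (3.40 ± 0.35), Dusp7 (3.20 ± 0.40), Rab32 (3.15 ± 0.41), Il6ra (3.13 ± 0.45), C3ar1 (3.07 ± 0.46), Nrp1 (2.78 ± 0.41) and Evi2a (2.68 ± 0.41). Of these, with cells thinned to 10000 transcripts Dusp7 was at 0.36 ± 0.52 (adjusted p = 0.920), Rab32 at 1.33 ± 0.58 (0.738), C3ar1 at 0.75 ± 0.57 (0.856), Nrp1 at 2.88 ± 0.75 (0.287) and Evi2a at 1.38 ± 0.57 (0.7002). Il6ra was not tested there. Dusp7 (2.33 ± 0.73, adjusted p = 0.0955) and Evi2a (2.14 ± 0.74, adjusted p = 0.165) lost the call without cells of other lineages. Under the same limits, among the largest falls besides Gata2 were those of Fabp3 (-4.22 ± 0.57), Ikzf2 (-3.45 ± 0.57), Car2 (-2.98 ± 0.33), Cpm (-2.87 ± 0.55), Kdelr3 (-2.54 ± 0.49), Timp3 (-2.47 ± 0.47), Cited4 (-2.15 ± 0.44) and Gata4 (-2.09 ± 0.32). With cells thinned to 10000 transcripts, none of the 5 of these still tested passed. Fabp3 was at -5.75 ± 1.42 (adjusted p = 0.215), Car2 at -1.75 ± 0.998 (0.823), Kdelr3 at -3.53 ± 1.13 (0.541), Timp3 at -3.03 ± 1.14 (0.637) and Gata4 at -2.79 ± 0.81 (0.394). Of these falls only that of Car2 became smaller. Fabp3, Cpm, Kdelr3 and Gata4 were not tested without cells of other lineages. Car2 encodes a carbonic anhydrase of red cells, and Gata4 is a transcription factor of endoderm and mesoderm. Of the 33 genes past the threshold that the rule for names picked, 12 lost the call when a library was left out. The adjusted p without library 1 was 0.0649 for Timp3 and 0.0547 for Npm1. Without library 2 it was 0.145 for Ptprc, 0.115 for Kdelr3 and 0.136 for Cited4. Without library 3 it was 0.429 for Itgam and 0.121 for Gata2, and without library 4 it was 0.126 for Ptprc, 0.0890 for Itgam, 0.0722 for Cpm and Timp3 and 0.0596 for Npm1.

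Of 17 lists, 4 were higher and 4 lower by camera, and none of these calls held with an estimated correlation. The marker, ribosome biogenesis and endoderm lists lost the call without cells of other lineages, where 3 lists were higher and 3 lower. The antigen presentation list was not among these, and Cd74 and H2-Ab1 were not tested there. The marker, macrophage, progenitor and ribosome biogenesis lists lost the call with cells thinned to 10000 transcripts. In that setting 0 lists were higher and 2 lower, so the chemokine and inflammation list was not called there either. Macrophage genes rose in 10 of 18 and fell in 1 (12 and 1 adjusted over the list alone; adjusted p = 1.34e-06), chemokine and inflammation genes rose in 3 of 6 (5 adjusted over the list alone; adjusted p = 0.000343), and progenitor genes fell in 3 of 12 and rose in 1 (5 and 2 adjusted over the list alone; adjusted p = 0.000515). For each of these 3 lists it was adjusted p = 0.284 with an estimated correlation. Ccl6 rose by 2.09 ± 0.50 (adjusted p = 0.0870 without library 3, and a change of -0.37 ± 0.61 with cells thinned to 10000 transcripts), and Lmo2, the progenitor gene that rose, by 1.46 ± 0.25. Lmo2 was at 0.39 ± 0.48 without cells of other lineages (adjusted p = 0.901) and at 0.46 ± 0.36 with cells thinned to 10000 transcripts (adjusted p = 0.862). Ribosome biogenesis genes rose in 8 of 20 (14 adjusted over the list alone; adjusted p = 6.88e-06), with Rrp9 up by 1.61 ± 0.33 and Npm1 by 0.58 ± 0.15 (adjusted p = 0.0547 without library 1 and 0.0596 without library 4). Rrp9 lost the call without cells of other lineages (1.14 ± 0.62, adjusted p = 0.638) and with cells thinned to 10000 transcripts (0.31 ± 0.50, adjusted p = 0.927). Npm1 did too (0.65 ± 0.62, adjusted p = 0.855, and 0.40 ± 0.17, adjusted p = 0.704). Erythroid genes fell in 3 of 9 (4 adjusted over the list alone; adjusted p = 1.40e-06), with Gata1 at -4.34 ± 0.59. Both had an adjusted p = 0.343 with an estimated correlation. Antigen presentation genes fell in 4 of 5 (4 adjusted over the list alone, adjusted p = 0.000627), with Cd74 at -3.01 ± 0.39 and H2-Ab1 at -2.34 ± 0.45 (adjusted p = 0.0603 without library 1 and 0.141 without library 3). Cd74 was at 361, 0, 228 and 18.8 CPM in the Kit cells of libraries 1 to 4. In library 2 it was not lower in the Cx3cr1 cells (0.624 CPM). Yolk sac endoderm genes fell in 4 of 19 (11 adjusted over the list alone; adjusted p = 2.70e-07), with Apoa1 at -0.82 ± 0.18 (adjusted p = 0.152 without library 1 and 0.0745 without library 3) and Ttr at -0.81 ± 0.17 (0.0911 and 0.0524). Without cells of other lineages Apoa1 was at 0.99, Ttr at 1.01 and the endoderm list turned upward (adjusted p = 0.964). Both lists had an adjusted p = 0.381 with an estimated correlation. The endoderm list took 1.24%, 1.57%, 2.72% and 1.24% of transcripts in the Kit cells of libraries 1 to 4 and 0.621%, 1.67%, 1.04% and 1.16% in the Cx3cr1 cells.

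The remaining lists did not pass. Lysosome genes rose in 2 and fell in 4 of 20 (the same adjusted over the list alone; adjusted p = 0.113, direction down). This list passed upward without cells of other lineages (adjusted p = 0.0384). Proliferation genes rose in 2 of 20 (5 adjusted over the list alone; adjusted p = 0.284) and dissociation stress genes in 1 of 12 (2 adjusted over the list alone; adjusted p = 0.488). Border macrophage genes rose in 3 and fell in 1 of 8 (the same adjusted over the list alone; adjusted p = 0.118), and microglia genes rose in 1 of 6 (2 up and 1 down adjusted over the list alone; adjusted p = 0.746). Megakaryocyte genes fell in 1 of 3 (2 adjusted over the list alone; adjusted p = 0.171, passed without cells of other lineages) and mesenchyme genes in 1 of 10 (1 down and 1 up adjusted over the list alone; adjusted p = 0.276). Granulocyte and monocyte genes rose in 1 of 9 (1 up and 2 down adjusted over the list alone; adjusted p = 0.909), with a median of 0.18 and a mean of -0.54. Endothelial genes rose in 1 of 5 (1 up and 2 down adjusted over the list alone; adjusted p = 0.759), with a median of 0.27, a mean of -0.27, a camera direction down and a fry direction up. Of the mast cell list 1 gene was tested and it fell, and of the lymphoid list 1 gene was tested and it did not pass.

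The set of calls depended on how the classes were made. Without cells of other lineages edgeR called 73 genes, of which 44 were among the 544, and with cells thinned to 10000 transcripts before classes were set it called 2, of which 0 were. Leaving out library 1, 2, 3 or 4 gave 349, 422, 358 or 339 calls, and 11.3% of calls were false in the simulation.

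Among the 153 Cx3cr1 cells, the comparison of 73 cells with an Mrc1 transcript with 80 cells without asked whether a subset resembling the Mrc1-positive macrophages of the borders of the nervous system is visible at this stage. Few genes separated these classes. C1qb and C1qc rose with Mrc1: C1qb from 207 ± 60.6 to 516 ± 115 CPM (SD, n = 4 libraries; log2 fold change 1.33 ± 0.14, SE; adjusted p = 0.000237) and C1qc from 57.1 ± 23.7 to 227 ± 81.2 CPM (1.98 ± 0.17; adjusted p = 4.35e-06). Gas6, a ligand of receptors for the uptake of dead cells, rose by 2.19 ± 0.32 and Ednrb, the endothelin B receptor, by 2.06 ± 0.28. In all, edgeR called 29 of 8184 genes, 26 higher and 3 lower in the Mrc1 cells. Median totals were 47045 transcripts in cells with Mrc1 and 11509 in cells without. Both classes differed in their clusters too: 46 of the 73 cells with Mrc1 lay in cluster 1 and 3 in the shallow cluster 0, against 24 and 17 of the 80 cells without.

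Among genes of at least 50 CPM, C3ar1, the receptor for complement C3a, rose by 1.64 ± 0.27 on the log2 scale, Hmox1, which degrades heme, by 1.20 ± 0.25, Rnf141 by 1.15 ± 0.21, Capg by 0.98 ± 0.21, Nme4 by 0.95 ± 0.20 and Tubb6 by 0.94 ± 0.18. Hp, which encodes haptoglobin, changed by -1.49 ± 0.23 and Cybb by -0.99 ± 0.17, and the other lower gene, BC100530, by -2.41 ± 0.30; it is outside the rule for names and was chosen after its values were seen. Each of these genes moved the same way in 4 of 4 libraries. Of the 6 marker genes tested, 0 passed, also adjusted over the list alone (camera adjusted p = 0.374): Ptprc differed by -0.00 ± 0.18, Itgam by -0.20 ± 0.23, Cd34 by -0.37 ± 0.23, Csf1r by 0.17 ± 0.12, Spi1 by 0.31 ± 0.17 and Runx1 by 0.55 ± 0.21. Of the 13 named genes past the threshold, 4 kept the call without each library (Gas6, Ednrb, C1qb and C1qc). Hmox1, Rnf141, Capg, Nme4 and Tubb6 lost it without library 1, 2 or 3 (adjusted p = 0.102 to 0.541). C3ar1 had an adjusted p = 0.132 and Hp an adjusted p = 0.0924 without library 1, and Cybb an adjusted p = 0.0685 without library 2 and 0.251 without library 3. Nme4 (0.80 ± 0.22, adjusted p = 0.104) and Cybb (-0.88 ± 0.22, adjusted p = 0.0621) lost the call without cells of other lineages, where Gas6 was at 3.46 ± 0.49. With cells thinned to 10000 transcripts C1qb (1.14 ± 0.19) and C1qc (1.59 ± 0.28) kept the call. Gas6 (1.92 ± 0.87, adjusted p = 0.792), C3ar1 (1.06 ± 0.39, 0.626) and Capg (0.98 ± 0.47, 0.796) lost it there. So did Tubb6 (0.95 ± 0.31, 0.378), Hp (-1.70 ± 0.71, 0.792) and Cybb (-0.79 ± 0.43, 0.825). Ednrb, Hmox1, Rnf141 and Nme4 were not tested there.

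**Figure D3:**
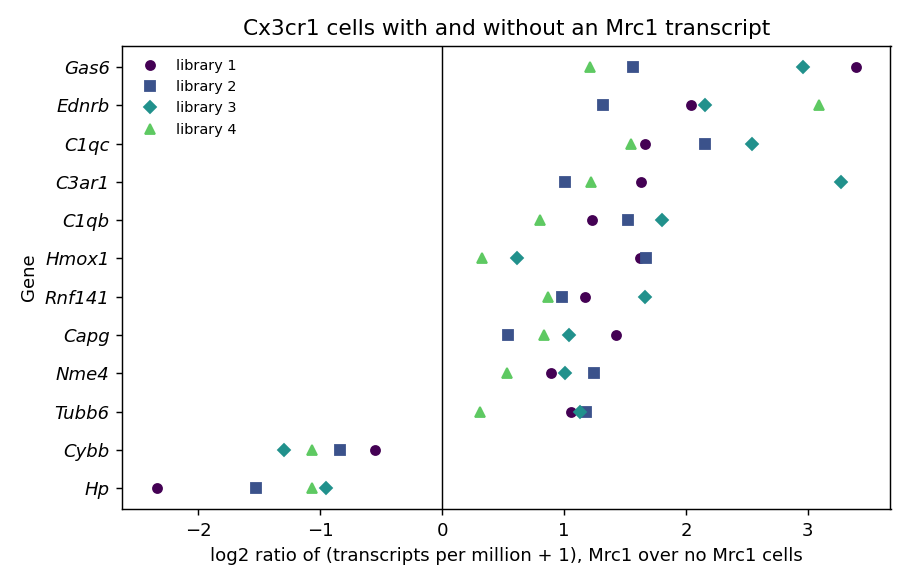
Log2 ratio of CPM plus 1 in Cx3cr1 cells with over those without an Mrc1 transcript (horizontal axis) for the 12 named genes past the threshold with at least 50 CPM (vertical axis), one point per A1/A2 library. All points of the 10 higher genes lie above 0 and all points of Hp and Cybb below 0.

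Of 16 lists, 2 were higher and 3 lower by camera, and none of these calls held with an estimated correlation. Border macrophage genes rose in 1 of 6 (5 adjusted over the list alone; adjusted p = 0.000301; adjusted p = 0.388 with an estimated correlation; fry adjusted p = 0.0253). Stab1, a scavenger receptor, rose by 2.55 ± 0.42 (adjusted p = 0.0870 without library 1 and 0.0685 without library 2), and Dab2 differed by 0.34 ± 0.08 (adjusted p = 0.122), but passed without cells of other lineages (0.69 ± 0.09; adjusted p = 2.34e-05) and with cells thinned to 10000 transcripts (1.04 ± 0.14; adjusted p = 9.65e-05). Macrophage genes rose in 5 of 17 (8 up and 2 down adjusted over the list alone; adjusted p = 0.000760). Antigen presentation genes fell in 0 of 4 (2 adjusted over the list alone; adjusted p = 0.0206), with H2-Ab1 at -1.84 ± 0.56 (adjusted p = 0.294) and H2-Eb1 at -1.01 ± 0.38 (adjusted p = 0.474). Yolk sac endoderm genes fell in 0 of 19 (1 adjusted over the list alone; adjusted p = 1.19e-07), with Lrp2 at -0.69 ± 0.19 and Epcam at -0.73 ± 0.30. These 3 lists had an adjusted p = 0.482 with an estimated correlation. Lysosome genes passed in 0 of 20, also adjusted over the list alone (adjusted p = 0.0474, direction down; adjusted p = 0.502 with an estimated correlation), with Ctsc at -0.45 ± 0.13 (-0.59 ± 0.12 and adjusted p = 0.0294 without cells of other lineages, where the list did not pass). The endoderm list took 0.358%, 1.41%, 0.692% and 1.27% of transcripts in cells with Mrc1 of libraries 1 to 4 and 0.923%, 1.96%, 1.78% and 0.769% in cells without.

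Microglia genes passed in 0 of 5 (1 up and 2 down adjusted over the list alone; adjusted p = 0.282). Chemokine and inflammation genes rose in 1 of 7 (2 adjusted over the list alone; adjusted p = 0.138, passed without cells of other lineages). In the lists that follow, 0 members passed over all genes. Adjusted over the list alone, 3 granulocyte and monocyte genes of 5 were lower and 1 was higher (camera adjusted p = 0.173), 1 proliferation gene of 20 was higher (adjusted p = 0.138), and 1 of 2 megakaryocyte genes was higher. Also adjusted over the list alone, 0 passed of 7 progenitor genes (adjusted p = 0.232), 6 erythroid genes (adjusted p = 0.145), 20 ribosome biogenesis genes (adjusted p = 0.173), 12 dissociation stress genes (adjusted p = 0.282), 4 endothelial genes (adjusted p = 0.138) and 10 mesenchyme genes (adjusted p = 0.0582). The lymphoid list had 1 tested gene, which did not pass, and the mast cell list 0.

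The count of calls moved with 1 library and with the model. Without library 4, edgeR called 135 genes, 51 higher and 84 lower, with all 29 among them, against 10, 11 and 14 without library 1, 2 and 3; without the library block it called 1, DESeq2 called 13, and 9.99% of calls were false in the simulation.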

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

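The tests of free RNA, of Y-linked molecules, of 2 cells in a well, of cells of other lineages, of depth and of splits, and the choice of the 3 patterns weighed, came after results were seen. The tests of barcode spill and of the spread of endoderm RNA were set before theirs.

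A library lay far from the other 3 of its group in 11 of 185 groups by Dixon's test of the gap over the range. Chance flags about 1 in 20 groups, so these 11 are near what chance brings. In the A1/A2 libraries Mrc1 was at 129.6 CPM in library 3 (84.3 to 84.5 in the others), F2r at 29.4 in library 4 (11.01 to 13.6), Adgrg1 at 10.5 in library 2 (26.1 to 27.5) and Nrgn at 29.99 in library 4 (14.7 to 16.9). In the EMP libraries Esam was at 17.3 CPM in library 2 (29.3 to 31.3 in the others). The log2 ratio of Cx3cr1 over Kit cells was -1.02 for Runx1 in library 4 (-0.10 to 0.05 in the others), -0.20 for Cited4 in library 3 (-2.77 to -2.58) and 0.98 for Npm1 in library 1 (0.44 to 0.48). The log2 ratio of cells with over those without Mrc1 was -1.06 for Itgam in library 4 (0.06 to 0.14 in the others), 0.31 for Tubb6 in library 4 (1.05 to 1.18) and 0.65 for Dab2 in library 1 (0.20 to 0.27).

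The A1/A2 libraries held neutrophil, monocyte and B cell transcripts. Free RNA in every well would spread partner genes alike, but the partner was at least 32.1 times as frequent in wells with the first gene (Cd79a with Cd79b 67.0, S100a8 with S100a9 32.1, Ly6c2 with Ccr2 68.7). Spill of barcodes is argued against for the B cell cluster, with more B cell molecules at the same well number of another library for 1 of its 18 wells. It was not tested for the neutrophil and monocyte clusters. Leukocytes of the mothers, which carry no Y chromosome, may be the source in the monocyte cluster. It held 7 Y-linked molecules, against 20.2 that the library-wide ratio of Y-linked to endoderm molecules brings (one-sided exact Poisson p = 0.9998). At the rate of cluster 1 there would be 17.7 (one-sided exact Poisson p = 0.00342 for fewer). All Poisson p-values here take molecules as independent, but these 7 lay in 4 wells. Of the 26 cells of this cluster, 14 came from library 3, while the rate of cluster 1 is pooled over libraries. The test therefore does not settle the source. The same test leaves the neutrophil cluster open (37 in 13 wells against 41.3, exact Poisson p = 0.768, and 30.4 at the rate of cluster 1). It goes against mothers as the only source in the B cell cluster (6 in 6 wells against 1.48, exact Poisson p = 0.00412), where counts are too few to decide.

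The background ratio in that test was chosen after a result was seen. A first version took the ratio of the endoderm-like cells as background for the 3 clusters together and gave an excess of Y-linked molecules, which argues against mothers as the source. With that ratio, 22.3 molecules would be brought in the neutrophil cluster (37 found, exact Poisson p = 0.00276 for an excess), 10.9 in the monocyte cluster (7 found) and 0.798 in the B cell cluster (6 found). The reading of the neutrophil cluster as open may rest on that choice: its p is 0.768 with the library-wide ratio.

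Endoderm transcripts were in wells of every cluster, with Afp in 95.4% of kept wells. Spread of endoderm RNA over the wells is a candidate explanation: 80 wells under 500 transcripts held a median endoderm share of 0.926%, 6.64 times the 0.139% of cluster 1. In cluster 5, with a median total of 85073 transcripts against 78059 for clusters 1 and 2 together, 2 cells in a well stay open: 7 of 27 wells held both 3 Y-linked and 3 Xist molecules, against 3 of 102 in cluster 1 (Fisher exact p = 0.000669), but deeper wells reach 3 molecules more often. With wells thinned to 40000 molecules, a test added after that p was seen, it was 2 of 25 against 1 of 56 (Fisher exact p = 0.224), too few to decide. No biological explanation was tested for either.

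Genes differed between cells with and without Mrc1. The clusters left out as other lineages are argued against as the whole cause, since 25 of the 29 genes were still called without them. That setting kept the shallow cluster 0, with 3 of the 73 cells with Mrc1 and 17 of the 80 cells without. A mix of cell types within the clusters kept was therefore not tested. For the 17 genes still tested at 10000 transcripts per cell, the median log2 fold change was 1.04 times that before thinning (0.95 against 0.92). Their median fold thus did not shrink at 1 depth, but single genes moved both ways. Among the named ones, C1qb, C1qc, C3ar1, Gas6, Capg and Cybb had smaller folds there (C3ar1 1.06 against 1.64). Hp and Tubb6 had larger ones. Only 3 of the 17 were still called. Thinning also drops shallower cells and sets the classes anew, and the genes were picked from the same data. Depth as a cause is therefore not settled. Among the 8 splits that part both sums of each library, 2 called as many genes, the real one with 29 included, and the highest other called 99; 8 splits are too few for a share under 0.05. That other split swaps library 4 and points to a structure of the sums, library 4 against the rest, as do the 135 calls without library 4. What makes library 4 differ stays open, and a biological subset of A2 cells was not tested apart from the Mrc1 transcript.

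For A1/A2 against EMP libraries, 1 of 35 splits, the real one, gave as many genes (3651, highest other 0). Every other split mixes both kinds of library, which raises the spread within its groups. That share is under 0.05 only if library numbers do not pair the libraries. With pairs kept, 8 splits part them all, too few for such a share. The labels name no animals, so chance differences between embryos were not tested. For Cx3cr1 against Kit cells, 1 of the 8 splits that part both sums of each library, the real one, gave as many (544, highest other 14), and 8 splits are too few for a share under 0.05.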

How the results depend on the processing

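Leaving out cells of other lineages, thinning to 10000 transcripts, summing identifiers and other scalings of the list tests were chosen after the data were seen. Except where a construction is named, the cause was not tested. Values are numbers of genes, log2 fold changes for genes and adjusted p for lists. A gene or list named here changed its direction in at least 1 of the settings given.

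For A1/A2 against EMP libraries (3651 genes), 786 were called without cells over 3 medians (460 of 3186 genes still tested changed sign, Nop16 among the named ones with -0.0350) and 121 with cells thinned to 1000, where fewer genes were tested. Leaving out a library gave 2596 to 4087 genes and 12 to 15 lists. Of 12 lists, 1 held with an estimated correlation. The border macrophage list had an adjusted p of 0.275 by fry, 0.781 without cells of other lineages and 0.591 to 0.998 without a library, and the lysosome list 0.358 to 0.990 without a library. Shares passed for 0 to 6 of 10 genes without a library, for 0 at 500 transcripts (the exact permutation smallest p is 0.0286), and for 0 in a sign-flip test by library number, whose smallest exact p is 0.125. These share tests say little on stability: at least 6 of 10 genes must reach a smallest p of 0.0286 for any to pass, and 0.125 cannot pass.

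A replicate block of library numbers gave 4950 genes (2519 up, 2431 down; 3620 of the 3651 among them), 13 lists and an adjusted p of 0.768 for the border macrophage list. The main fit did not pair libraries by number: correlations of same-number libraries were 0.22, 0.39, -0.02 and 0.22. However, 3 of 4 A1/A2 and 3 of 4 EMP libraries correlated best with their own number. Titles number both groups alike and the labels name 384-well plates, so libraries of a number may share a plate. Whether they do is not stated, so pairing stays open. The main counts of genes and lists and the permutation test of shares leave out such pairs. Runx1, not called in the main fit, was lower in the A1/A2 library of all 4 numbers.

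For Cx3cr1 against Kit cells (544 genes, 8 lists), DESeq2 called 288, requiring Csf1r gave 855, and leaving out a library gave 339 to 422 genes and 8 to 9 lists. Thinning gave 2 at 1000 and 2 at 10000 transcripts, where 2 lists passed, Itgam was at -0.45, Ccl6 at -0.37 and Apoa1 at 0.0233; fewer cells were in the classes. Without cells of other lineages the Kit sums held only 1 to 6 cells and 73 genes were called. Cd34 was at -0.25, Apoa1 at 0.99 and Ttr at 1.01 there. Adjusted p was 0.0384 for the lysosome list, which then passed upward, 0.408 for the proliferation and 0.964 for the endoderm list. Clusters on part of the molecules do not test this contrast: the one with the highest Kit level, at 0.297 per 10000, had 25 cells, all of cluster 6 with its monocyte genes, and it gave Ptprc -0.97, Itgam -0.68, Csf1r -0.32, Runx1 0.15, C3ar1 -0.000383, Nrp1 -0.39 and Ccl6 -0.22. An estimated correlation left 0 lists. The endothelial list had an adjusted p of 0.772 by fry, 0.851 without the block and 0.122 to 0.952 without a library; the microglia list 0.672 without the block; the granulocyte and monocyte list 0.980 with library totals and 0.0107 (without library 3, where it passed) to 0.647 without a library.

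For cells with against without Mrc1 (29 genes, 5 lists), DESeq2 called 13, no filter 127, no block 1, cells thinned to 10000 gave 7, cells without other lineages 49 and leaving out a library 10 to 135 genes and 2 to 5 lists. An estimated correlation left 0 lists, fry 1 and thinning to 10000 2. Ptprc was at 0.0437 with library totals, 0.0392 without a filter, 0.00775 with Csf1r required, 0.0137 in cells of 2000 or more transcripts and -0.237 to 0.128 without a library; Itgam was at -0.308 to 0.0925 without a library and Runx1 at -0.18 with cells thinned to 10000. Thinning to 10000 gave an adjusted p of 0.808 for the progenitor, erythroid and ribosome biogenesis lists; the last had 0.699 without cells of other lineages, the erythroid list 0.0700 to 0.589 and the marker list 0.119 to 0.9501 without a library.

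Of the other values of genes, 916, 443 and 304 in the 3 comparisons kept direction and side of the threshold, 16, 77 and 54 were weaker and 3, 3 and 9 stronger. For lists these were 219, 141 and 134 kept, 13, 18 and 18 weaker and 9, 7 and 5 stronger, and for shares 74 kept, 43 weaker and 3 stronger. Clusters numbered 6 at resolution 0.3 and 11 at 1.0. Not run: the series table for A1/A2 against EMP, since it holds A1/A2 wells only. The filter on Kcnq1ot1 removed 0 cells, so it tested nothing, and thinning to 1000 gave no value for the Mrc1 classes.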
